A study of Mus musculus with 4 samples.

How the data were processed

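H3K4me3 was immunoprecipitated from primary bone marrow-derived macrophages of mice with a mixed background of C57BL/6 (94%) and 129/Ola (6%), per the labels' protocols. Chromatin was fixed with 1% formaldehyde for 10 min and incubated with 10 ug of antibody. The design crossed 2 genotypes with 2 treatments, and each of the 4 groups held 1 library. Nothing in the labels says how many animals contributed to a library.

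The authors deposited 1 peak list per library. Reads were aligned with Bowtie to the mm9 mouse genome, per the submitters' processing notes. Peaks were called with MACS, per the file headers, and the word input in the headers points to an input DNA control. The versions, the p-value threshold and the numbers of reads are not given in the sources used here. Each peak has a start, an end and a score, which the authors deposited as the peak caller gave it. By the convention of MACS the score is a negative multiple of the log10 of the peak's p-value, and the lowest scores in the lists, 50 to 50.03, then correspond to a p-value of 1e-05. From 8874 to 9636 peaks per list have a score of exactly 3100, and 45 to 76 lie between 3100 and 3233.06. The smallest p-value that double precision can store gives a score of 3233.06, so a score of exactly 3100 most probably marks a p-value stored as 0. Peaks of 3100 or above were therefore treated as 1 class, called the ceiling, and ordered by width within it. The score grows with depth and enrichment. It was used to rank or filter peaks within a list and to class joined regions by their highest score, so counts per class set between genotypes also depend on the unknown depths. Because peaks were called in each library separately, an absent peak means that the region did not pass the caller's threshold, and not that H3K4me3 was absent.

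Overlaps were computed with bedtools 2.31.1 with a minimum of 1 bp. For each pair of lists, the peaks of one list without an overlapping peak in the other were counted, over all peaks and in 4 score classes. The peaks of the 4 lists were also joined into regions wherever they overlapped, and each region was classed by the lists that had a peak in it. Shares are given with 95% Wilson intervals from scipy 1.17.1, and a count of 0 with the limit that 3 counts would give. These cover counting error over peaks, and not the variation between cultures or mice. Groups came from the sample titles. With 1 library per group no test between groups was run.

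The overlap counts were checked on simulated data, a copy of the list of untreated Wbp7+/- cells shifted by a few bases with 200 of its 17316 peaks removed. The pairwise overlap and the 4-list classes each recovered 200 of the 200 removed peaks, with 0 false losses in the pairwise overlap. Each kept peak overlapped its own copy by construction. The check therefore covers the counting only and gives no rate of false losses between separate libraries. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

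The regions named were set by a rule made before the data were examined: the 20 highest-scoring regions of each class, by position. The classes are regions found in both Wbp7+/- lists only, in both Wbp7-/- lists only, in both LPS lists only, in both untreated lists only, and gained with LPS in Wbp7+/- without a peak in LPS-treated Wbp7-/- cells. The reference score was that of untreated Wbp7+/- cells for regions in both Wbp7+/- lists only and in both untreated lists only, of untreated Wbp7-/- cells for regions in both Wbp7-/- lists only, and of LPS-treated Wbp7+/- cells for the gained classes. The order by width at the ceiling, the 4 score classes and the loci drawn were chosen after the data were seen. The text prints all 20 for the first class and the leading ones for the rest.

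The alternatives set before the data were examined were another overlap minimum, a tolerance of 1 kb, a score of at least 100, lists of equal length and the peaks at or above the median score of a list, which are those at the ceiling. Joining peaks within 1 kb, keeping ceiling regions alone and leaving out the LPS-treated Wbp7+/- list were added after seeing the data. The promoter comparisons and gene lists planned for this series, which included genes of GPI anchor synthesis, LPS-induced cytokines and macrophage identity, were not run. They need a gene annotation of mm9, and the gene table used here is of GRCm38, so no gene is named for any region and coordinates are those of the lists.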

Results

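Histone H3 trimethylated on lysine 4 (H3K4me3), a mark found mainly at active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary mouse macrophages grown from bone marrow for 7 days. By their genotype labels, the cells had 1 functional copy of Wbp7 (Wbp7+/-) or none (Wbp7-/-). Wbp7, also called Kmt2b, encodes a methyltransferase that acts on lysine 4 of histone H3. Each genotype was sampled untreated and after 4 h with 10 ug/ml lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages. The 4 groups held 1 library each, so no difference described here has a replicate check and no p-value between groups was computed. The 2 treatments gave separate libraries of each genotype, and presence in both is the only measure of repeatability.

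The Wbp7+/- lists held 17316 peaks untreated and 17313 after LPS, and the Wbp7-/- lists held 14599 and 15086. The covered length differed less, at 34.51 and 34.93 Mb in Wbp7+/- and 33.47 and 33.9 Mb in Wbp7-/-. The median peak width was 1768 bp untreated and 1740 bp after LPS in Wbp7+/-, against 2106 and 2026 bp in Wbp7-/-. Peaks of 5 kb or more numbered 557 and 657 in Wbp7+/- and 566 and 658 in Wbp7-/-. Scores pile up at a ceiling of 3100, which most probably marks p-values too small to be stored, and 9695, 9480, 9047 and 8950 peaks of the 4 lists, in the order given, stood at 3100 or above. Read numbers are unknown, so the depth behind a missing peak cannot be given. The intervals below are 95% Wilson intervals and cover counting error over peaks only.

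The first comparison asked which H3K4me3 regions depend on Wbp7. In untreated cells, 3410 of 17316 Wbp7+/- peaks had no overlapping peak in Wbp7-/- cells, a share of 19.7% (19.11 to 20.29). In LPS-treated cells the number was 3412 of 17313, a share of 19.7% (19.12 to 20.31). In the other direction, 1012 of 14599 untreated Wbp7-/- peaks lacked a Wbp7+/- peak (6.93%, 6.53 to 7.36), and 1207 of 15086 did after LPS (8.00%, 7.58 to 8.44). For comparison, the turnover between treatments within a genotype was 7.47% for untreated Wbp7+/- peaks without an LPS peak and 6.48% for untreated Wbp7-/- peaks without an LPS peak. The unmatched Wbp7+/- peaks were narrow, with a median width of 766 bp untreated and 777 bp after LPS. The genotype lists differ in length, and with each list limited to its 14599 highest-scoring peaks the untreated numbers were 1694 Wbp7+/- peaks and 1756 Wbp7-/- peaks without a counterpart.

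The share of missing peaks depended on peak score, and the difference between the directions was present in every score class. Scores grow with depth, which is unknown, so a class does not hold peaks of equal strength in each genotype. The classes therefore do not separate genotype from depth. Among untreated Wbp7+/- peaks, 66.8% of those scoring under 100 had no Wbp7-/- peak, 46.8% of those from 100 to under 500, 22.4% of those from 500 to under 3100, and 0.722% of those at the ceiling. For untreated Wbp7-/- peaks without a Wbp7+/- peak, the shares were 37.9%, 17.9%, 2.99% and 0%. At the ceiling, 70 of 9695 untreated Wbp7+/- peaks (0.572 to 0.911%) had no Wbp7-/- counterpart. By contrast, 0 of 9047 untreated Wbp7-/- peaks lacked a Wbp7+/- counterpart, which allows a share of up to 0.0332%. After LPS the corresponding numbers were 82 of 9480 and 1 of 8950. None of the 9695 ceiling peaks of untreated Wbp7+/- cells was missing from the LPS list of the same genotype, which allows a share of up to 0.0309%.

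**Figure D1:**
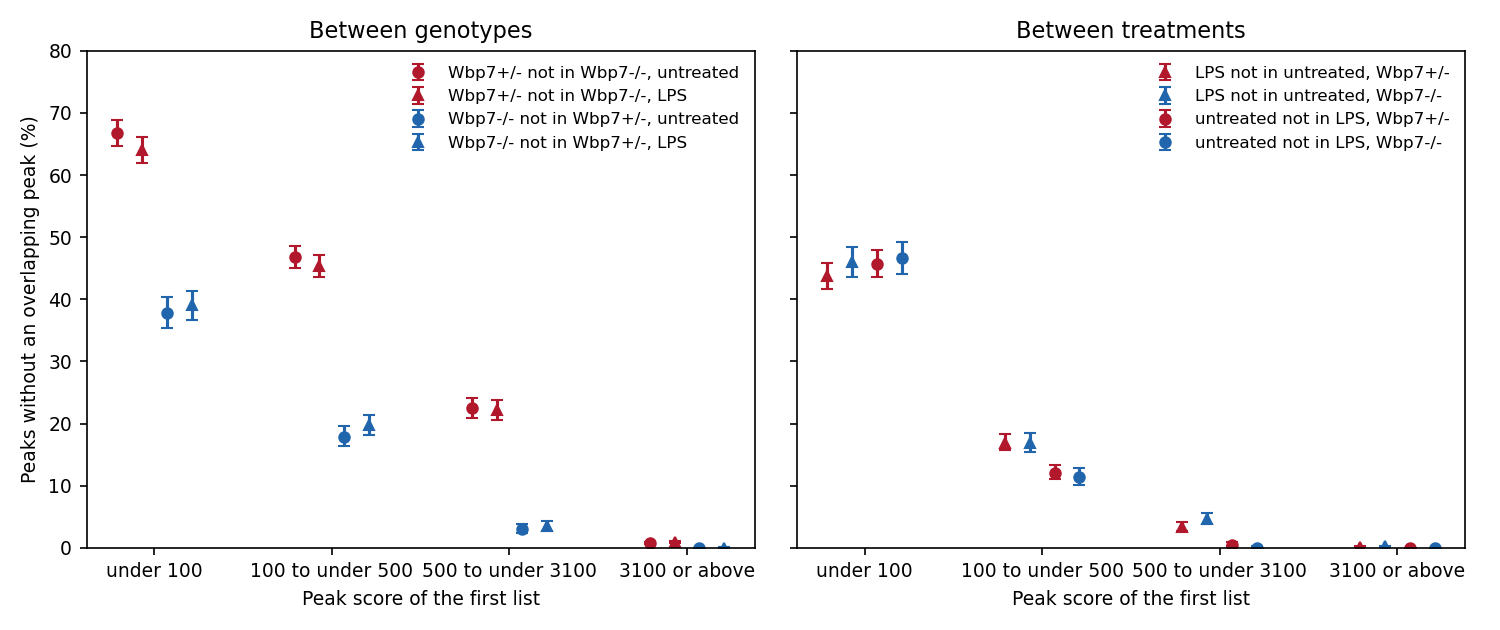
Percentage of peaks without an overlapping peak in a second list (vertical axis) by the score of the peak (horizontal axis, 4 classes), between genotypes (left) and between treatments (right), with 95% Wilson intervals for counting error over peaks and 1 library per group. Between genotypes the Wbp7+/- points (red) lie above the Wbp7-/- points (blue) in each class, at 22.4% against 2.99% for untreated peaks scoring 500 to under 3100, whereas between treatments the genotypes lie close together. Scores depend on the unknown depth of each library, so a class does not match peak strength between genotypes.

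Joining overlapping peaks of the 4 lists gave 18786 regions, of which 12294 (65.4%) had a peak in every list. A peak was present in both Wbp7+/- lists and in neither Wbp7-/- list at 2047 regions, 13.6% (13.1 to 14.2) of the 15039 regions found in both Wbp7+/- lists. The reverse, a peak in both Wbp7-/- lists and in neither Wbp7+/- list, was seen at 388 regions, 2.96% (2.69 to 3.27) of 13092. Pairs of lists that share neither genotype nor treatment held fewer such regions, but they give no measure of a sensitivity common to both libraries of a genotype. Peaks were present at 48 regions in untreated Wbp7+/- and LPS-treated Wbp7-/- cells alone and at 20 in LPS-treated Wbp7+/- and untreated Wbp7-/- cells alone, and none of these scored 500 or above. Of the 2047 Wbp7+/- regions, 623 scored 500 or above and 82 reached the ceiling, against 54 and 0 of the 388 Wbp7-/- regions, with scores from libraries of unknown depth. With lists of equal length, 1211 regions were in both Wbp7+/- lists only and 745 in both Wbp7-/- lists only. Cutting the weaker Wbp7+/- peaks turns shared regions into regions in the Wbp7-/- lists only, so the 745 do not measure a gain.

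The 82 ceiling regions restricted to Wbp7+/- cells lay on 19 of the 20 chromosomes represented, with none on the X chromosome. Their median width was 1911 bp, and none was as wide as 5 kb. Among the 9185 regions at the ceiling in both Wbp7+/- lists, 55 (0.599%, 0.460 to 0.779) had no peak in either Wbp7-/- list and a further 14 had a peak in only 1 of these. Positions are given in mm9, counted from 1. The widest was on chromosome 11 from 48666121 to 48671022, where peaks covered 4493 bp in untreated and 3955 bp in LPS-treated Wbp7+/- cells. On chromosome 19, the region from 12084362 to 12088216 carried 3839 and 3777 bp. On chromosome 4 the region from 28739474 to 28743069 carried 3329 and 3596 bp, and on chromosome 12 that from 53703288 to 53706606 carried 3319 and 3114 bp. The region on chromosome 17 from 23685679 to 23688670 held peaks of 2992 and 2776 bp, and that on chromosome 8 from 83401813 to 83405176 held 2920 and 3175 bp. Peaks of 2880 and 3130 bp lay on chromosome 5 from 125884758 to 125887887, the only one of the 20 named regions below the ceiling after LPS, with a score of 2722.06.

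Some of these regions lay close together and beside regions that kept their peak, at loci chosen after the data were seen. These loci do not stand for the class. Over all regions in both Wbp7+/- lists only, the median distance to the nearest region of all 4 lists was 33.0 kb. Of these regions, 12.2% lay within 5 kb of one. On chromosome 13, the regions from 21250623 to 21253836 and from 21258566 to 21262625 had peaks in both Wbp7+/- lists only. A neighbouring peak, from 21270719 to 21274197 in untreated Wbp7+/- cells, was at the ceiling in all 4 lists. On chromosome 11, the regions from 68852565 to 68855418 and from 68934446 to 68937987 were also restricted to Wbp7+/- cells. Between them, the peak from 68883335 to 68885176 in untreated Wbp7+/- cells was again at the ceiling in all 4 lists.

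The remaining named regions of this class were narrower, with peaks of 2060 to 2474 bp in untreated Wbp7+/- cells. They lay on chromosome 16 from 94591214 to 94593687, on chromosome 5 from 34338166 to 34340637, on chromosome 15 from 57806518 to 57808913 and on chromosome 11 from 58114646 to 58117006. Others were on chromosome 3 from 122431655 to 122434109, on chromosome 6 from 137596033 to 137598316 and on chromosome 9 from 42912748 to 42915115. The last were on chromosome 13 from 9275291 to 9277414 and on chromosome 1 from 181889485 to 181891577. All of these were at the ceiling in both Wbp7+/- lists. Genes at these positions, the Wbp7 locus among them, were not analysed here, because no mm9 gene annotation was used.

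**Figure D2:**
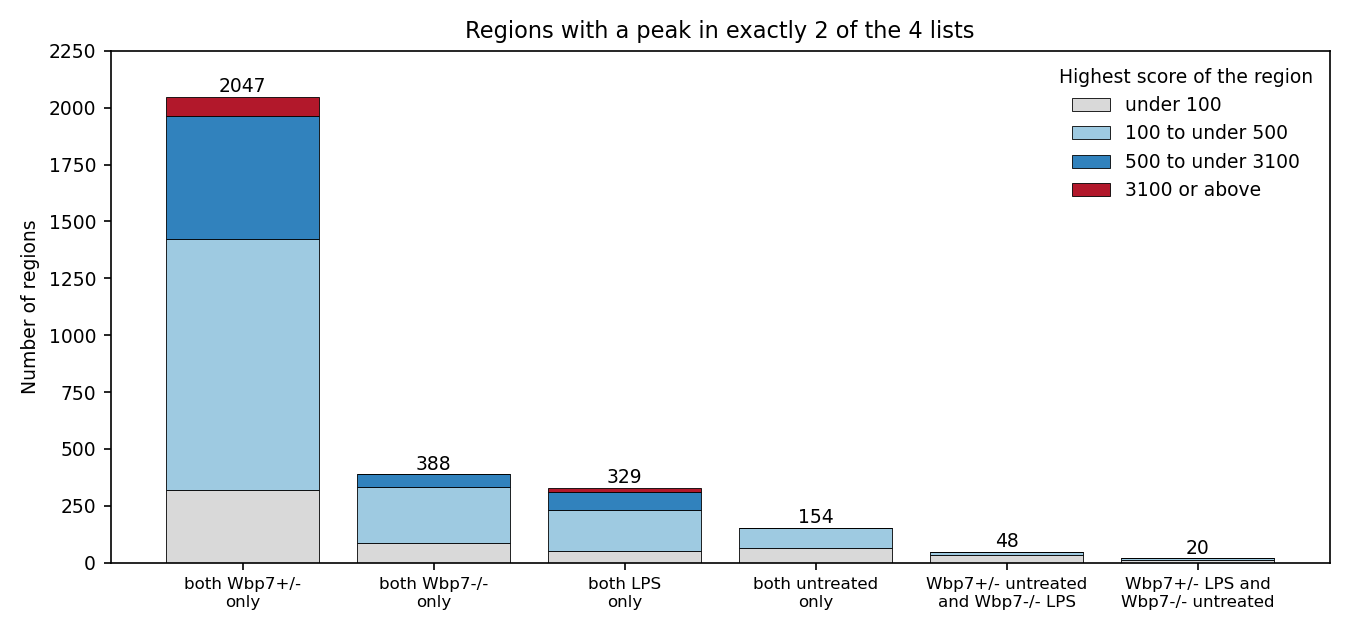
Number of regions (vertical axis) with a peak in exactly 2 of the 4 lists, for each pair of lists (horizontal axis), divided by the highest score in the region. The pair of Wbp7+/- lists shares 2047 such regions, 82 of them at the ceiling, and the pair of Wbp7-/- lists 388, none at the ceiling, while the pairs that share neither genotype nor treatment hold 48 and 20.

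**Figure D3:**
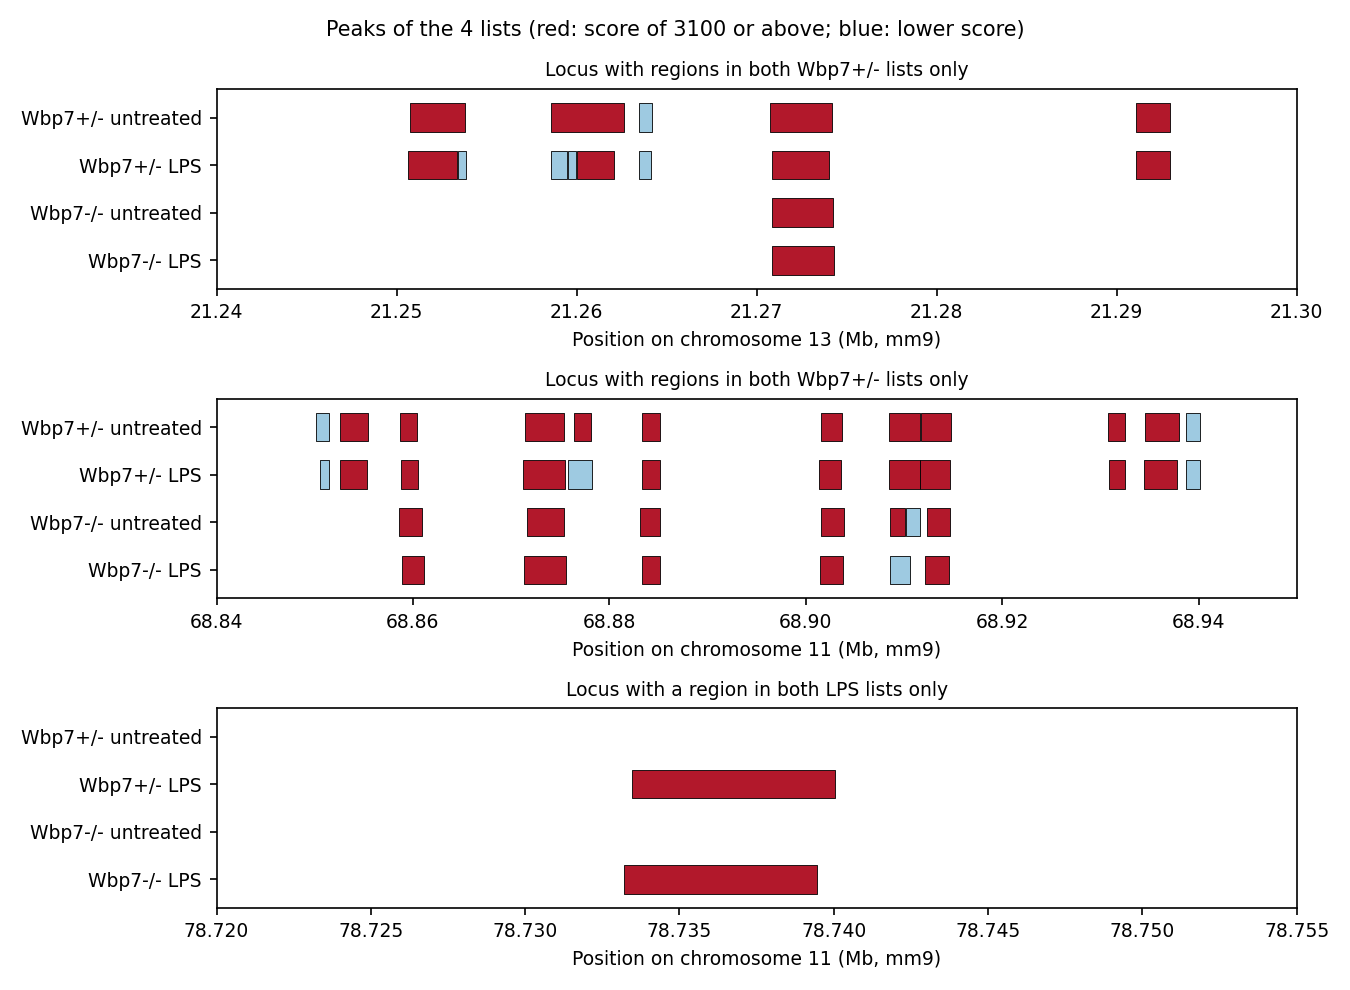
Peaks of the 4 lists (rows) drawn to scale along the chromosome (horizontal axis, Mb, mm9), in red where the score was 3100 or above and in blue where it was lower. On chromosomes 13 and 11 the Wbp7+/- lists hold ceiling peaks that have no Wbp7-/- counterpart beside peaks present in all 4 lists, and in the bottom panel the peak from 78733216 to 78740026 on chromosome 11 is present in the LPS lists alone.

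None of the 388 regions with a peak in both Wbp7-/- lists alone reached the ceiling. The highest-scoring was on chromosome 13 from 4277587 to 4278861, with scores of 2636.32 untreated and 1835.37 after LPS and widths of 1275 and 1106 bp. The next was on chromosome 7 from 132773630 to 132775866, with scores of 1899.05 and 1176.84. The regions on chromosome 17 from 48178146 to 48179454 and on chromosome 4 from 46804121 to 46805938 followed, with 1389.39 and 1294.57 in untreated cells. The 20 named regions of this class had untreated scores from 774.94 to 2636.32, all below the ceiling.

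The second comparison asked which H3K4me3 regions appear after 4 h of LPS. In Wbp7+/- cells 1550 of 17313 LPS peaks (8.95%, 8.54 to 9.39) had no overlapping untreated peak, and 1293 of 17316 untreated peaks (7.47%, 7.09 to 7.87) had no LPS peak. In Wbp7-/- cells the numbers were 1297 of 15086 (8.60%, 8.16 to 9.06) and 946 of 14599 (6.48%, 6.09 to 6.89). Most of these were low-scoring, and 43.8% of LPS peaks scoring under 100 in Wbp7+/- and 46% in Wbp7-/- lacked an untreated peak. At the ceiling, 20 of 9480 LPS peaks were new in Wbp7+/- and 20 of 8950 in Wbp7-/-, whereas 0 of 9695 and 0 of 9047 untreated ceiling peaks were missing after LPS. With each list limited to its 14599 highest-scoring peaks, the order of the genotypes turned, with 875 new peaks in Wbp7+/- and 1033 in Wbp7-/-. This limit cuts more low-scoring peaks from the Wbp7+/- lists, so the turned order is no measure of the LPS response. With peaks under 100 dropped from every list, new peaks numbered 998 in Wbp7+/- and 805 in Wbp7-/-. The file of the LPS-treated Wbp7+/- library names 24 h in its first line, whereas its sample label and the Wbp7-/- file give 4 h, so the LPS time of that library is uncertain.

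New peaks after LPS were shared by the genotypes at 329 regions, which had a peak in both LPS lists and in neither untreated list. Regions gained in Wbp7+/- numbered 1399 and those gained in Wbp7-/- 1151. The reverse, a peak in both untreated lists alone, was seen at 154 regions. Of the 329 shared gains, 99 scored 500 or above and 17 reached the ceiling, against 3 and 0 of the 154 shared losses. The ceiling gains were broad, with a median width of 3542 bp, and 5 of the 17 were 5 kb or wider.

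The widest shared gain was on chromosome 11 from 117835263 to 117842148, with a peak of 6871 bp in Wbp7+/- and 6377 bp in Wbp7-/- cells. Chromosome 11 also held gains from 78733216 to 78740026, with 6564 and 6240 bp, and from 83339644 to 83344609, with 4515 and 4445 bp. On chromosome 2, the gain from 129130831 to 129137390 measured 6560 bp in Wbp7+/- and 4854 bp in Wbp7-/- cells, and that from 30755616 to 30759353 measured 3699 and 3164 bp. On chromosome 17 the gain from 34994305 to 34999735 measured 5394 and 4825 bp. These gains were at the ceiling in both LPS lists, as were those on chromosome 8 from 59983742 to 59987283 and on chromosome 5 from 30339556 to 30342479 and from 92789099 to 92791832. Other gains were at the ceiling in Wbp7+/- and lower in Wbp7-/- cells. The gain on chromosome 18 from 75117238 to 75122534 scored 2979.43 in Wbp7-/- cells and that from 60535697 to 60539051 scored 1502.53. On chromosome 3 the gains from 78974114 to 78977477 and from 19857004 to 19861040 scored 2280.33 and 1209.01 there. Scores depend on the depth of each library and measure no change between the genotypes.

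The shared losses after LPS were narrow and low-scoring. The highest-scoring was on chromosome 16 from 84621253 to 84621917, with scores of 639.04 in untreated Wbp7+/- and 134.06 in untreated Wbp7-/- cells. The next by the untreated Wbp7+/- score, on chromosome 1 from 138581953 to 138582795, scored 519.26 and 318.14.

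The last comparison asked whether LPS-dependent regions of Wbp7+/- cells also appear without Wbp7. Of the 1399 regions gained with LPS in Wbp7+/- cells, 402 (28.7%, 26.4 to 31.2) had a peak in LPS-treated Wbp7-/- cells and 997 had none. Of the 997, 977 had a peak in the LPS-treated Wbp7+/- list alone, and 688 of these 977 scored under 100. A peak in untreated Wbp7-/- cells was present at 93 of the 1399 (6.6%, 5.5 to 8.1). The class of 997 numbered 427 with lists of equal length, 641 with peaks under 100 dropped from every list and 632 with peaks joined within 1 kb. Dropping peaks also makes new gains and absences, so the 427 and 641 need not be parts of the 997. In the reverse direction, 782 of the 1151 regions gained in Wbp7-/- cells (67.9%, 65.2 to 70.6) had a peak in LPS-treated Wbp7+/- cells, and 501 (43.5%, 40.7 to 46.4) had one in untreated Wbp7+/- cells. The Wbp7+/- lists are longer and the depths unknown, so the difference between the directions cannot be assigned to Wbp7. The overlap of Wbp7+/- gains depended on score. Of 568 gains scoring 100 or above, 274 (48.2%, 44.2 to 52.4) had a Wbp7-/- LPS peak, as did 92 of 107 (86.0%, 78.2 to 91.3) scoring 500 or above and 18 of 19 at the ceiling (94.7%, 75.4 to 99.1). The share with a Wbp7-/- LPS peak also rose with score among all Wbp7+/- LPS peaks. It was 36.0% under 100, 54.7% from 100 to under 500, 77.8% from 500 to under 3100 and 99.1% at the ceiling. The ceiling gain without a Wbp7-/- peak lay on chromosome 1 from 173696956 to 173699585, with a width of 2630 bp. The next by score were on chromosome 2 from 167640955 to 167642971 (score 1707.3), on chromosome 15 from 6823187 to 6824703 (1599.94), on chromosome 9 from 7272251 to 7274623 (1581.24) and on chromosome 2 from 70346508 to 70347999 (1545.88). Of the 20 ceiling regions gained with LPS in Wbp7-/- cells, all had a peak in LPS-treated Wbp7+/- cells, and 11 had one in untreated Wbp7+/- cells as well. Of the 19 ceiling gains in Wbp7+/- cells, 1 had a peak in untreated Wbp7-/- cells. Whether the LPS response differed between the genotypes was not tested, since each had 1 library per treatment.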

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

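The regions below were picked out because the peak calls with and without LPS differed in opposite directions in the genotypes. At 20 regions Wbp7+/- cells gained a peak with LPS and Wbp7-/- cells lost one, and at 48 regions the reverse was seen. The difference was not tested, since each genotype had 1 library per treatment. All 68 scored below 500, with a highest score of 392.3, and 48 of them scored under 100. Calls at such scores often differed between lists. Of untreated peaks scoring under 100, 45.69% in Wbp7+/- and 46.65% in Wbp7-/- cells had no LPS peak. Groups of 1 library allow no check for outlying samples.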

How the results depend on the processing

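Of 54 alternative values, 29 stayed within 1.5 times the reported count and 25 did not, and the ceiling-only, 1 kb joining and left-out-list alternatives were chosen after the data were seen. The 25 include every alternative kept to ceiling regions or to peaks at or above the median score. These alternatives count a part of the reported set and can only give lower counts. Requiring 50% of a peak to be covered and accepting peaks within 1 kb moved no pairwise count beyond that factor. With lists of equal length, unmatched Wbp7+/- peaks numbered 1694 untreated and 1845 after LPS, unmatched untreated Wbp7-/- peaks 1756, and LPS gains 875 in Wbp7+/- against 1033 in Wbp7-/-. By construction this trims the longer Wbp7+/- lists more. Equal lengths also bring the unmatched counts of the 2 directions close to each other, so they do not test the pairwise excess of Wbp7+/- peaks. These counts were 1694 against 1756 in untreated cells and 1845 against 1662 after LPS. Regions in both Wbp7+/- lists only then numbered 1211, in both Wbp7-/- lists only 745, in both untreated lists only 87, and Wbp7+/- gains absent from Wbp7-/- LPS 427. Among peaks at or above the median score of each list, unmatched Wbp7+/- peaks numbered 70 untreated and 82 after LPS, unmatched Wbp7-/- peaks 0 and 1, and LPS gains 20 in each genotype. At the ceiling, 82 regions were in both Wbp7+/- lists only, 0 in both Wbp7-/- lists only, 17 in both LPS lists only, 0 in both untreated lists only, and 1 Wbp7+/- gain was absent from Wbp7-/- LPS. Dropping peaks under 100 from every list gave 998 LPS gains in Wbp7+/- and 805 in Wbp7-/-, and 641 Wbp7+/- gains absent from Wbp7-/- LPS. With this filter, a peak whose only counterpart in the other list scores under 100 counts as gained or absent. In the lists as deposited, 568 regions gained in Wbp7+/- scored 100 or above. Wbp7+/- gains absent from Wbp7-/- LPS numbered 632 when peaks within 1 kb were joined. Without the LPS-treated Wbp7+/- list, LPS-only regions became 725 and untreated-only regions 406, because each then rests on 1 list fewer. The promoter windows, the protein-coding filter and the gene-list draws were not run, for want of an mm9 annotation. No paired analysis was possible because the groups share only 1 replicate number and the reported counts come from no test. Unknown read numbers limit every statement about an absent peak, most of all below a score of 100.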

Other observations

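The tests of chromosome 7, of weak peaks alone in their region, of neighbouring losses, of unmatched weak peaks and of the 24 h time, and the comparisons of width and distance, were chosen after the data were seen. Over the 12294 regions that every list shared, the median log2 width ratio of LPS to untreated was -0.036 in Wbp7+/- (SD 0.293) and -0.031 in Wbp7-/- cells (SD 0.291). A small set differed from this. Of these regions, 53 had at least 2 times the untreated width after LPS in both genotypes and 4 were narrower by at least 2 times. On chromosome 2, the peaks from 34806967 to 34821594 covered 5688 bp untreated and 14035 bp after LPS in Wbp7+/- cells, and 5544 and 14083 bp in Wbp7-/- cells. On chromosome 7, the region from 133734834 to 133743517 went from 1853 to 7808 bp in Wbp7+/- and from 998 to 8529 bp in Wbp7-/- cells. Its untreated scores were 430.48 in Wbp7+/- and 52.81 in Wbp7-/- cells, the latter close to the lowest scores in the lists. On chromosome 9, the region from 20818377 to 20827375 went from 3564 to 8870 bp and from 3423 to 8999 bp.

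Partial differences between the genotypes were seen where all 4 lists had a peak. In both treatments, 52 shared regions were narrower in Wbp7-/- than in Wbp7+/- cells by at least 2 times and 29 were wider by as much. The width of a called peak can also depend on the unknown depth of its library. On chromosome 1, the region from 136311124 to 136317713 covered 5658 and 6097 bp in Wbp7+/- cells and 2472 and 2509 bp in Wbp7-/- cells, untreated and after LPS. On chromosome 17, the region from 46164159 to 46170043 covered 5885 and 5690 bp against 2299 and 2498 bp. In the other direction, the region on chromosome 9 from 44141618 to 44146178 covered 2047 and 1874 bp in Wbp7+/- and 4561 and 3779 bp in Wbp7-/- cells. Over all shared regions the median log2 width ratio of Wbp7-/- to Wbp7+/- was 0.047 untreated (SD 0.316) and 0.052 after LPS (SD 0.341).

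The median distance of regions in both Wbp7+/- lists only to the nearest region of all 4 lists was 33.0 kb, and 12.2% (10.9 to 13.7) lay within 5 kb of one. The share within 5 kb was 21.1% (17.4 to 25.5) for regions in both Wbp7-/- lists only, 32.5% (27.7 to 37.8) for those in both LPS lists only, and 26.2% (22.9 to 29.8) for regions in the untreated Wbp7+/- list alone. Among regions scoring 500 or above the intervals of the genotypes overlapped, at 7.71% (5.86 to 10.1) for both Wbp7+/- lists only and 11.1% (5.19 to 22.2) for both Wbp7-/- lists only.

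A shallower or less enriched Wbp7-/- library may account for missing peaks. For the 70 ceiling peaks missing from untreated Wbp7-/- cells, the lists argue only against a fall in sensitivity that acts alike on all regions. Such a fall removes weak peaks before strong ones. Yet 33.2% of the Wbp7+/- peaks scoring under 100 had a Wbp7-/- peak, above the 25% set as the bound. Among regions with a single such peak, with no stronger Wbp7+/- peak in the region, the share was 28.1% (25.7 to 30.6), and it was 74.99% (73.1 to 76.8) for single peaks of 500 to under 3100. A fall that differs between regions was not tested, and the ceiling hides differences in strength among its peaks. In the LPS list of the same genotype, 54.3% of untreated Wbp7+/- peaks under 100 had a peak, so a smaller fall stays possible. For peaks under 100 without a counterpart, sensitivity and genotype cannot be told apart. The lists carry no read numbers, and the 1694 unmatched peaks at equal list lengths do not measure depth. A direct effect of Wbp7 on these weak regions stays open and untested.

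Because the mice had a mixed background, strain-derived segments might carry the regions restricted to Wbp7+/- cells. The 16 windows of 10 Mb richest in them, 6% of 275, held 16.1% of these regions, below the 25% set as the bound. The 16 windows richest in regions found in both Wbp7+/- lists, whether or not in Wbp7-/-, held 16.03% of those. These values bear only on a few large segments that would hold most of the regions. Short or scattered segments, or segments behind a part of the regions, could not be detected this way. A segment linked to Wbp7 on chromosome 7 cannot hold the 1930 regions on other chromosomes. The 117 on chromosome 7 were 11.2% (9.44 to 13.3) of its 1043 regions found in both Wbp7+/- lists, against 13.6% over all chromosomes. For these 117, linkage and loss of Wbp7 cannot be told apart, since a short segment would not move the share of a whole chromosome. Among regions found in both Wbp7+/- lists, 311 pairs of consecutive regions more than 5 kb apart were both restricted to Wbp7+/- cells. The number was above the highest of 10000 random placements within chromosome and score class (299, mean 244.6). No upper limit was set on the distance, and a run of 4 consecutive restricted regions on chromosome 7 spanned 1478.1 kb. What makes consecutive regions alike, such as scattered strain segments, shared CpG content, local gene families or loss that spreads, was not tested.

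The 24 h in the first line of the LPS-treated Wbp7+/- file could explain regions gained with LPS in Wbp7+/- cells alone, if that library was in fact taken later. Time and genotype cannot be told apart in these regions, since each genotype has 1 LPS library. Of the 19 Wbp7+/- gains at the ceiling, 18 also had a peak in the Wbp7-/- LPS library.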
